A study of Arabidopsis thaliana with 4 samples.

How the data were processed

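Root RNA of Arabidopsis thaliana was sequenced in 4 libraries, 1 for each combination of genotype and treatment. Per the labels, the genotypes were wild type (accession Col-0) and a double mutant of the auxin response factor genes ARF10 and ARF16, and about 500 seedlings, 6 days old, were moved to a 2% nutrient solution at pH 5.0 with 0 or 10 µM AlCl3. Roots were collected after 24 h, total RNA was extracted with a column kit and libraries followed a standard Illumina protocol. The aligner, the counting program, the genome build, the strand setting and the treatment of reads shared by similar genes are not given in the sources used here.

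The deposited count table gives whole numbers of reads per transcript model, named by locus identifier and model number, with an empty mark where no read was counted (15308 cells over 25092 models). The deposited RPKM table gives reads per kilobase of model, scaled to the column total. Each RPKM value, divided into its count and column total, returned a whole-number model length within 0.01 bp for 100% of models, so both tables hold the same reads. The deposited p-value columns for detection were empty (0 values given) and were not used. Counts of the models of a locus were summed, which gave 22284 loci, 2515 of them with more than 1 model listed. Names, product descriptions and neighbouring genes came from the RefSeq annotation of TAIR10.1, matched by locus identifier (99.3% matched, 9053 with a symbol); no coordinates are printed because the authors' build is not known. Loci with several annotated models had fewer reads: the median over the 4 libraries was 147 reads for loci with 1 model, 54 for 2, 32 for 3 and 19 for 4 or more, so absolute levels of genes with many models are uncertain. Members of gene families can share reads, and overlapping or antisense genes cannot be separated without the strand setting.

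Total counts were 2232186 reads in wild type without Al, 2188782 in the library labelled arf10/16 without Al, 2280894 in wild type with Al and 2080348 in the library labelled arf10/16 with Al. Loci were kept by edgeR's filterByExpr over the 4 groups (14739 loci). Library sizes were scaled by TMM. Each pairwise value is a log2 ratio of CPM with a prior count of 2. With 1 library per group there is no replicate and no test of any pairwise difference, so a rule of size was used: a gene counts as higher or lower if its log2 ratio is at least 1 in size and the exact 95% counting interval of the ratio excludes 1. The interval is Clopper-Pearson on both counts and covers counting error only, not the spread between plants or cultures. A fold against a library at 0 was computed against a floor of 3 counts in that library and is given as "at least". The difference of Al responses is the log2 ratio in the pair labelled arf10/16 minus that in wild type, with the same rule and an interval from the 4 counts plus 0.5.

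The only test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in an additive model of genotype and treatment over the 4 libraries, with Benjamini-Hochberg adjusted p at a threshold of 0.05. It sets 2 libraries against 2 on 1 residual degree of freedom and takes the part of the data that departs from additivity as its error, so any true difference in response enters that error. "Rose" and "fell" below are kept for genes past this test. The SE given with its effects is the absolute log2 effect divided by the square root of the test's F value, not a spread between replicates. The common dispersion was 0.0259 (coefficient of variation 0.161). In simulated libraries with 200 changed genes among 14739, the test recovered 28% of 2-fold and 86% of 4-fold Al effects with 3 false calls, and 31% and 93% of genotype effects with 4 false calls. The rule of size recovered 38% of 2-fold and 95% of 4-fold changes for Al in wild type, and 44% and 92% for Al in the pair labelled arf10/16. All these simulated libraries had the same dispersion for every gene and no difference of response between the genotypes. The recovery and the false calls therefore do not cover genes whose response differed, or a spread that varies by gene.

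Before the data were examined, 29 gene lists were fixed: aluminium tolerance and STOP1 targets, auxin biosynthesis, auxin transport, early auxin response, other auxin response factors, ethylene, cytokinin, xyloglucan endotransglucosylase/hydrolases, expansins, pectin enzymes, cellulose and callose synthases, root hair, root cap, root stem cell niche, starch synthesis, Casparian strip and suberin, cell cycle, DNA damage, glutathione S-transferases, reactive oxygen enzymes, phosphate starvation, iron deficiency, jasmonate, immune response, dehydration and abscisic acid, phenylpropanoids, heat shock, photosynthesis as a shoot marker, and reference genes. They name 502 loci, of which 377 were measured above the filter. Some reference genes were nearly without reads: UBQ10 had 1, 0, 1 and 1 reads in the libraries in the order above, and PP2AA3 1, 1, 0 and 0. Whether reads of such loci were lost in counting was not tested, so a gene below the filter is not shown to be unexpressed. A list is described by its median log2 ratio and by that median's percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Of the lists, 8 held genes with a library at 0; with those genes at their bound, 7 medians moved, by at most 0.35.

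Named genes followed a rule fixed at the same time: ARF10 and ARF16; for each comparison the 5 highest and 5 lowest log2 values among genes with a symbol, past the rule of size and with at least 50 reads in 1 library; the 5 smallest p in each direction of the additive test; up to 4 members of each list past the rule of size with the largest change; and set genes as values, among them ALMT1, MATE, ALS3, TAA1, TAR2 (below the filter, no ratio), PIN2, AUX1 and the reference genes. Names are those of the reference, so PIN2 appears as EIR1. Genes named after their values were seen are marked as such. In the closing section, 18 families taken from product descriptions and lists of clock genes and of senescence and autophagy genes were chosen after the main results.

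Alternatives were DESeq2 size factors (DESeq2 1.42.0), scaling by total counts, no filter, a prior count of 0.5, an interval wholly beyond 1.5-fold, the deposited RPKM as log2(RPKM + 0.1), DESeq2's Wald test and limma-trend (limma 3.58.1) in the additive model. Loci with a single annotated model, and models kept apart, were added after the data were seen. Under total counts the median of all genes moved to -0.085 for Al in wild type, -0.084 for Al in the pair labelled arf10/16, -0.125 for genotype without Al and -0.055 for genotype with Al; under TMM these medians lay between -0.015 and 0.040. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest.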

Results

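The data are 4 root transcriptomes of Arabidopsis thaliana seedlings, from wild type and from a line labelled as the arf10/arf16 double mutant (arf10/16 below), each after 24 h in acidic nutrient solution with 0 or 10 µM AlCl3. Aluminium ions in acid solution stop root growth, and ARF10 and ARF16 are transcription factors of the auxin response. The title of the series names a different response of the double mutant to Al as its subject. Each of the 4 groups has 1 library of 2080348 to 2280894 reads, so no comparison below has replicates, and the intervals of single genes cover counting error only.

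ARF10 was 38.6-fold higher in the untreated library labelled arf10/16 than in wild type (95% counting interval 32.0 to 47.1), and 21.9-fold higher with Al (18.5 to 26.1). It had 110 reads in wild type and 3820 in the library labelled arf10/16 without Al, and 142 and 2640 with Al. ARF16 was 2.01-fold lower in the untreated library labelled arf10/16 (1.51 to 2.70; 159 against 71 reads) and 1.56-fold lower with Al (1.05 to 2.33; 75 against 41 reads). In the additive model, edgeR's quasi-likelihood test gave a genotype effect of 4.86 ± 0.26 (log2, SE; adjusted p = 0.000477) for ARF10 and -0.85 ± 0.22 (adjusted p = 0.0915) for ARF16. The level of ARF10 goes against the label, since it was higher in both libraries of the line labelled as its mutant. Gene-level counts do not show which part of the transcript was read or whether a working protein was made. For that reason the libraries are called by their labels, in the short form, throughout, and every direction between genotypes below rests on those labels.

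**Figure D1:**
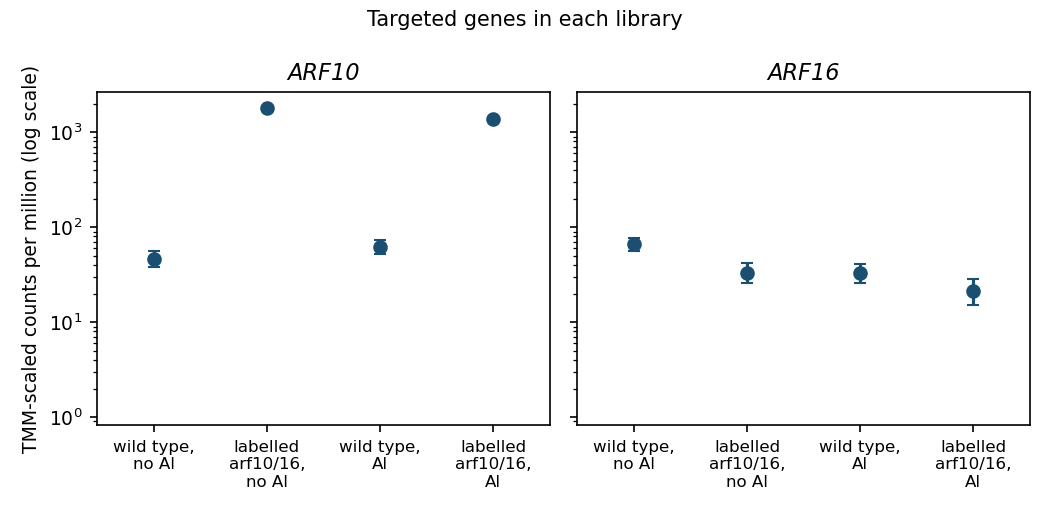
Reads of ARF10 (left) and ARF16 (right) in each of the 4 libraries, as TMM-scaled CPM on a log axis; bars are exact 95% Poisson intervals and cover counting error only. ARF10 stands at 1782 and 1364 in the libraries labelled arf10/16 against 46.1 and 62.4 in wild type, while ARF16 is highest, at 66.7, in untreated wild type.

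The first comparison asks what Al did to wild-type roots. Of 14 Al tolerance genes 9 were higher and none lower with Al, and all 15 root hair genes were lower. ALMT1, the malate channel that releases organic acid to bind Al, was 107-fold higher (54.2 to 249), with 8 reads without and 819 with Al. The ferric reductase FRO2 was 97.7-fold lower (69.1 to 143), and the iron transporter IRT1 was 58.0-fold lower (30.3 to 128). The beta-glucosidase gene DIN2, known to respond to darkness and sugar starvation, was 114-fold higher (81.3 to 165). By the rule of size, 2122 genes were higher and 1782 lower among 14739, against 202 and 198 in simulated unchanged libraries with the estimated dispersion. Which direction had more genes depends on the scaling: total counts gave 1914 higher and 2059 lower, and the RPKM 2188 and 2419.

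Further genes with a symbol at the extremes in wild type were PRX52, a peroxidase, at least 117-fold higher with no read without Al, and AATP1, an ATPase, 118-fold higher (78.6 to 187). PUB54, a U-box protein, was 115-fold higher (60.5 to 253). FRO4, a second ferric reductase gene, was 70.8-fold lower (49.1 to 106). The sulfate transporter gene SULTR1;1 went from 163 reads to 1 (156-fold lower, 27.5 to 6183), and CYP705A3 from 165 reads to 1 (158-fold lower, 27.9 to 6259).

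The same question was put to the pair labelled arf10/16. ALMT1 went from 1 to 342 reads (379-fold higher, 67.5 to 15005). FRO2 was 40.6-fold lower (28.9 to 58.8), IRT1 36.6-fold lower (19.1 to 80.7) and DIN2 74.2-fold higher (61.3 to 90.7). PBS3, an acyl-adenylase of salicylic acid synthesis, was 96.1-fold higher (63.9 to 152), and the cysteine protease gene CEP1 was 71.3-fold higher (40.6 to 139). ZAT7, a zinc finger protein, was at least 45.4-fold higher, with no read without Al. The ferric reductase gene FRO5 was 47.9-fold lower (33.4 to 71.2), and HR2, a homologue of a mildew resistance gene, went from 75 reads to 1 (67.7-fold lower, 11.8 to 2710). By the rule of size 1597 genes were higher and 1387 lower, against 205 and 187 in simulated unchanged libraries; total counts gave 1452 and 1583, and the RPKM 1757 and 2012, with more genes lower.

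Across genes, the Al responses of both pairs correlated with r = 0.81 (Spearman's rho 0.73) over 14739 genes, which are not independent replicates. Of the genes past the rule of size, 1252 were higher and 941 lower in both pairs, against 398 in the same direction expected from independent lists, and 4 went in opposite directions. Among these 2193 shared genes, 1508 (68.8%) had the larger change in wild type; the median absolute log2 ratio was 2.09 in wild type and 1.73 in the pair labelled arf10/16. The pairs share no library.

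**Figure D2:**
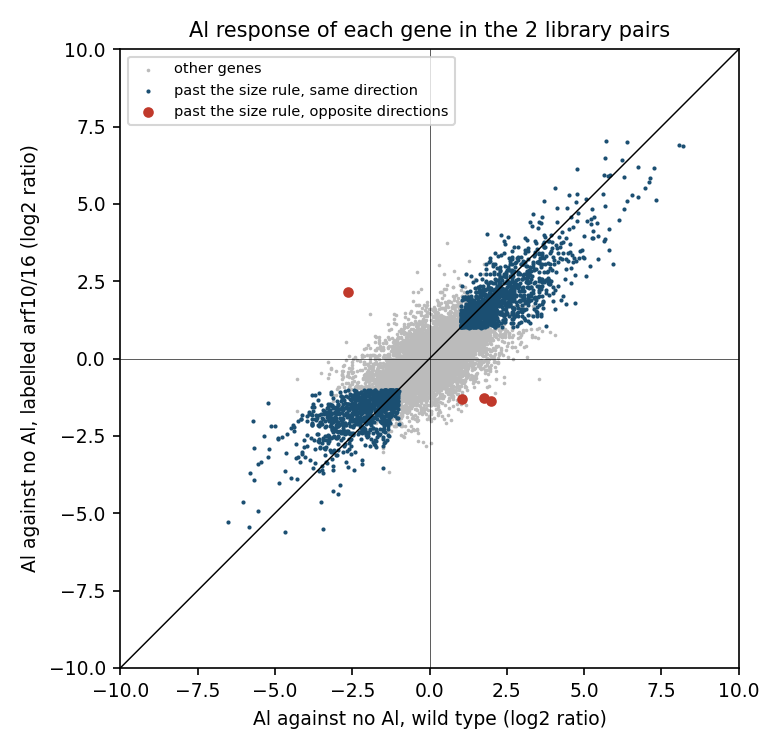
Log2 ratio of Al against no Al for each gene in wild type (horizontal axis) and in the pair labelled arf10/16 (vertical axis); blue points are the 2193 genes past the rule of size in the same direction in both, red points the 4 in opposite directions, and the diagonal marks equal responses. The blue points run along the diagonal and most of them lie nearer to 0 on the vertical axis.

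Over both genotypes, 2278 genes rose and 1924 fell with Al in edgeR's quasi-likelihood test of the additive model; DESeq2's Wald test gave 1053 and 696, and limma-trend on the RPKM 1673 and 1737. Among genes with a symbol, those with the smallest adjusted p in edgeR's quasi-likelihood test included DIN2 (6.49 ± 0.25 on the log2 scale, adjusted p = 1.67e-05), ALMT1 (7.11 ± 0.34), PBS3 (6.19 ± 0.28), CEP1 (5.99 ± 0.26), the beta-glucosidase gene BGLU25 (4.91 ± 0.21) and the dehydration protein gene LEA4-5 (6.75 ± 0.32), all rising with the same adjusted p. IRT1 (-5.53 ± 0.28, adjusted p = 1.92e-05 in edgeR's quasi-likelihood test), FRO2 (-5.98 ± 0.33), the nitrate transporter gene NRT2:1 (-4.20 ± 0.24), the iron regulator gene FRU (-3.72 ± 0.22) and the glutamate receptor gene GLR2.3 (-3.70 ± 0.24) fell.

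Of the fixed lists, Al tolerance and STOP1 targets had a median log2 ratio of 1.64 in wild type and 1.45 in the pair labelled arf10/16 (both at percentile 100 of the matched random lists). Of its 14 measured members 11 rose and 1 fell in edgeR's quasi-likelihood test; here and below, the count adjusted over the list alone was the same unless it is given. WRKY46 rose (7.19-fold, 5.33 to 9.87, in wild type; 5.35-fold, 4.46 to 6.45, in the other pair), as did the glutamate dehydrogenase genes GDH1 (4.73-fold, 4.01 to 5.60, and 5.82-fold, 4.88 to 7) and GDH2. The MATE transporter gene AT1G51340, of citrate release, had no read in either untreated library and 13 and 10 reads with Al (at least 4.54- and 3.69-fold higher). ALS3 was at 20 reads with and without Al in wild type and at 6 and 20 in the libraries labelled arf10/16.

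Root hair genes were lower with Al in every case in wild type (15 of 15, median -2.74) and in 12 of 15 in the pair labelled arf10/16 (median -1.78), and all 15 fell in edgeR's quasi-likelihood test. RSL2, a regulator of hair growth, was 21.6-fold lower in wild type (8.98 to 67.7) and 6.02-fold lower in the other pair (3.65 to 10.5); the wall protein gene PRP3 was 9.33-fold (7.57 to 11.6) and 3.46-fold lower (3.01 to 3.99). Shoot marker genes of photosynthesis moved the same way with smaller size: their medians were -0.55 and -0.81, and 3 of 10 fell (4 adjusted over the list alone). The Casparian strip and suberin list split: 13 of 20 rose and 6 fell, and the medians of 1.56 and 1.48 hide that CASP1 was 9.67-fold lower in wild type (7.44 to 12.8) and CASP2 7.84-fold lower (5.28 to 12.1), both genes of the strip's membrane scaffold, while FAR4, of suberin synthesis, was 6.81-fold higher (2.36 to 26.8).

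The 4 wall lists had medians below 0 with Al in both pairs. Of 22 xyloglucan endotransglucosylase/hydrolases, 6 rose and 10 fell (6 and 13 adjusted over the list alone; medians -0.81 and -0.47); XTH24 was 40.1-fold higher in wild type (32.2 to 50.7) and XTH16 8.87-fold lower (5.37 to 15.6). Of 15 expansins 2 rose and 7 fell (medians -0.19 and -0.57), with the root hair expansin EXPA18 11.7-fold lower in wild type (5.71 to 27.8) and EXLB1 6.83-fold higher (5.64 to 8.33). Of 7 pectin enzymes 1 rose and 4 fell (2 and 5 adjusted over the list alone; medians -0.58 and -0.59), and the polygalacturonase gene PGAZAT rose, 42.9-fold in wild type (18.1 to 134). Of 10 cellulose and callose synthases 1 rose and 7 fell (1 and 9 adjusted over the list alone; medians -0.92 and -0.65); CESA2 was 3.01-fold lower in wild type (2.64 to 3.44), and the callose synthase GSL05 was the gene that rose.

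Among hormone genes, the early auxin response list had medians of 0.83 in wild type and 0.60 in the pair labelled arf10/16, and 10 of 25 rose and 2 fell (10 and 3 adjusted over the list alone). GH3.3, which conjugates auxin, was 13.6-fold higher in wild type (6.93 to 30.5) and 5.54-fold higher in the other pair (3.21 to 10.2), and BRU6, another GH3 gene, 11-fold (8.66 to 14.3) and 2.91-fold higher (2.49 to 3.4); AXR3 fell. In auxin transport 2 of 13 rose and 4 fell (medians 0.17 and -0.17). EIR1, the PIN2 carrier of epidermis and root cap, was 5.03-fold lower in wild type (3.99 to 6.41) and 2.29-fold lower in the other pair (1.91 to 2.75). AUX1, an auxin importer (log2 -0.12 and -0.17), did not pass the test. In auxin biosynthesis 0 of 12 rose and 2 fell (medians 0.34 and -0.46); TAA1 had log2 ratios of -1.28 and -0.39. Of 8 other auxin response factors 1 rose and 1 fell (medians 0.32 and -0.13): MP was 8.20-fold higher in wild type (6.54 to 10.4), and ARF18 fell. Of 13 cytokinin genes 1 rose and 8 fell (1 and 10 adjusted over the list alone; medians -1.20 and -0.81), with the response regulator ARR6 4.35-fold lower in wild type (2.08 to 10.2). Of 18 ethylene genes 4 rose and 3 fell (medians 0.21 and 0.13); EFE, which makes ethylene, and ACS7 rose.

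Of 15 iron deficiency genes 4 rose and 9 fell (5 and 9 adjusted over the list alone; medians -0.93 and -0.88). Of 17 phosphate starvation genes 5 rose and 3 fell (medians 0.04 and 0.27), with PHT1;1, a phosphate importer, 6.92-fold lower in wild type (6.14 to 7.83) and SPX3 3.48-fold higher (3.11 to 3.90). Of 31 glutathione S-transferases 11 rose and 5 fell (12 and 5 adjusted over the list alone; medians 1.15 and -0.02), with GSTU22 44.7-fold higher in wild type (25.4 to 87.1). Of 10 reactive oxygen genes 5 rose and 2 fell (medians 1.40 and 0.57), with CAT1 9.44-fold higher (7.34 to 12.3) and FSD1 19.7-fold lower (12 to 35). Of 11 dehydration genes 6 rose (7 adjusted over the list alone; medians 1.82 and 0.60), with KIN1 12.4-fold higher (8.77 to 18) and NCED3, of abscisic acid synthesis, 10.6-fold higher (6.08 to 19.8). All 3 measured heat shock genes rose (medians 1.24 and 1.49). Of 10 phenylpropanoid genes 1 rose and 4 fell (medians -0.28 and -0.52).

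The remaining lists were the jasmonate list (1 of 15 rose and 1 fell), the immune list (3 of 12 rose and 2 fell), root cap (2 of 8 rose), starch synthesis (1 of 4 rose) and the cell cycle (0 of 24 rose and 1 fell; 0 and 0 adjusted over the list alone). None of 7 stem cell niche genes (medians -0.16 and -0.41) and none of 7 DNA damage genes (medians -0.40 and 0.01) passed edgeR's quasi-likelihood test. Among reference genes ACT2 fell (-1.42 ± 0.21, adjusted p = 0.0017 in edgeR's quasi-likelihood test); GAPC1 (-0.28), PEX4 (-0.21), AT4G34270 (0.27) and AT2G28390 (0.15) did not pass.

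Without Al, 14 of 15 jasmonate genes and 9 of 12 immune response genes were higher in the library labelled arf10/16 than in wild type. IGMT1, a methyltransferase of indole glucosinolates, was 26.9-fold higher (18.1 to 41.9), and CYP81F2, a P450 of the same pathway, 15.4-fold higher (11.6 to 21). CYP706A2 was 16.5-fold higher (12.1 to 23.1), and the receptor kinase gene CRK11 15.7-fold higher (11 to 23.3). BARS1, a triterpene synthase, was 9.46-fold lower (5.90 to 16.0), XTH5 4.87-fold lower (2.61 to 9.90), and RTFL16, LSU2 and sks15 were 4.15-, 3.90- and 3.79-fold lower. In total 1173 genes were higher and 383 lower, against 204 and 209 in simulated unchanged libraries. The share higher among these was 75.4% with TMM and 61.7% with scaling by total counts.

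Jasmonate genes were higher in 14 of 15 cases (median 1.98; percentile 100), among them LOX3 (11-fold, 5.05 to 28.3), JAZ6 (8.22-fold, 6.25 to 11), LOX4 (7.72-fold, 5.31 to 11.6) and TIFY10B (7.28-fold, 5.85 to 9.16), which encode an enzyme of jasmonate synthesis or a repressor of its response. Of 12 immune response genes 9 were higher (median 1.93; 1.58 with the gene at 0 reads set to its bound), among them MYB51 (5.84-fold, 4.98 to 6.88), WRKY40 (5.25-fold, 4.33 to 6.40), WRKY33 (4.74-fold, 4.44 to 5.06) and WRKY53 (4.70-fold, 3.83 to 5.80). Of 31 glutathione S-transferases 7 were higher and 1 lower (median 0.52; 0.49 with the gene at 0 reads at its bound), GSTF7 by 6.01-fold (5.39 to 6.72), and the oxidase gene RBOHD was 4.89-fold higher (4.37 to 5.49). Phosphate starvation genes had a median of -0.79, below all random lists, with 2 of 17 past the rule of size (MGDC 2.92-fold, 1.28 to 7.47, and PLDP2 2.08-fold lower, 1.78 to 2.44). Cell cycle genes had a median of -0.62, also below all random lists, with CYCB1;1 2.53-fold lower (1.40 to 4.79) and CYCA1;1 2.5-fold lower (1.33 to 4.99). Root hair genes had a median of 0.25 with none of 15 past the rule, and photosynthesis genes a median of 0.38 with 1 of 10 higher.

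With Al, the library labelled arf10/16 had higher root hair genes than wild type. Of 15 root hair genes 12 were higher (median 1.39; percentile 100): PRP1 was 4.94-fold higher (3.01 to 8.50), RSL2 4.23-fold (1.52 to 14.6), RHD6 3.46-fold (1.96 to 6.40) and SHV2 3.42-fold (2.05 to 5.91). Photosynthesis genes were higher in 4 of 10 cases in the same comparison (median 0.68). IAA33, an atypical auxin repressor, was 20.8-fold higher (6.74 to 104; 3 against 53 reads), CSLB02 9.41-fold (3.34 to 36.6), AGP30 5.73-fold (3.63 to 9.40) and the extensin gene EXT12 5.14-fold (3.71 to 7.24). In total 607 genes were higher and 261 lower, against 213 and 214 in simulated unchanged libraries; the share higher was 69.9%, and 55.3% under total counts.

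Lower in that comparison were GDU2 (4.16-fold, 2.48 to 7.34), CYP71B26 (4.46-fold, 1.51 to 17.9), LSU4 (4.11-fold, 2.45 to 7.26), FRO5 (3.66-fold, 2.44 to 5.64) and the thioredoxin gene TH8 (3.27-fold, 1.98 to 5.65). ALMT1 was 2.04-fold lower (1.79 to 2.32), although the Al tolerance list as a whole had a median of 0.01. EIR1 was 2.33-fold higher (1.78 to 3.05) and TAA1 2.25-fold higher (1.03 to 5.16). Jasmonate and immune genes were again higher, at smaller size: 5 of 15 (median 1.01; 0.76 with the gene at 0 reads at its bound) and 6 of 12 (median 1.0). Phosphate starvation genes had a median of -0.42, below all random lists, with IPS1, a non-coding RNA of the phosphate response, 2.01-fold lower (1.82 to 2.22).

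Between the treatments, 230 genes were higher and 48 lower in the libraries labelled arf10/16 both times, against 55.1 expected from independent lists, and 12 went in opposite directions (r = 0.39 and rho 0.35 across genes). In edgeR's quasi-likelihood test of the additive model 274 genes were higher and 45 lower in the libraries labelled arf10/16; DESeq2's Wald test gave 170 and 6, and limma-trend on the RPKM gave 0, against 2208 before adjustment. Among genes with a symbol that were higher, the smallest p after ARF10 in edgeR's quasi-likelihood test belonged to the transcription factor genes RRTF1 (2.3 ± 0.22, adjusted p = 0.0101), WRKY40 (2.15 ± 0.21) and WRKY30 (2.26 ± 0.23) and to PROPEP3, precursor of an elicitor peptide (1.96 ± 0.20). XTH31 (-1.37 ± 0.20, adjusted p = 0.0265 in edgeR's quasi-likelihood test), LSU4 (-1.97 ± 0.28), CYP71B26 (-1.86 ± 0.28), BARS1 (-3.24 ± 0.35) and PEPC1 (-1.41 ± 0.22) were lower.

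By list, that test found 5 of 15 jasmonate genes (13 adjusted over the list alone) and 7 of 12 immune genes higher (10 higher and 1 lower adjusted over the list alone). It found 1 of 17 phosphate starvation genes lower (12 adjusted over the list alone), 0 of 15 root hair genes (4 higher adjusted over the list alone) and 0 of 10 reactive oxygen genes (4 higher adjusted over the list alone). It found 0 of 24 cell cycle genes (0 adjusted over the list alone), and of 31 glutathione S-transferases 0 higher and 1 lower (1 and 1 adjusted over the list alone); the median of the latter with Al was -0.06. In the early auxin list 1 of 25, ATAUX2-11, was lower (-1.01 ± 0.20, adjusted p = 0.0458 in edgeR's quasi-likelihood test). None of the 10 photosynthesis genes passed.

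**Figure D3:**
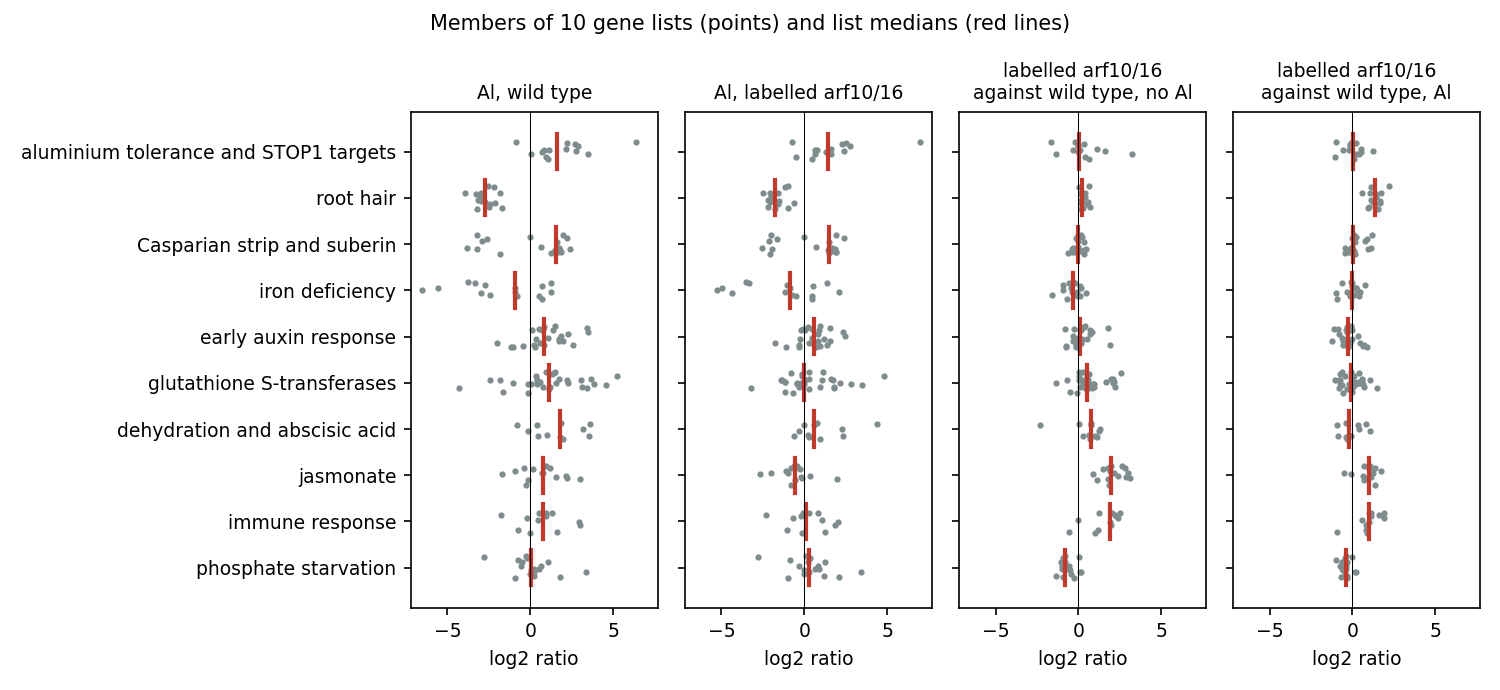
Log2 ratios of the measured members of 10 fixed gene lists (points, spread vertically for sight) and the list medians (red lines) in the 4 pairwise comparisons, 1 panel each; the horizontal axis is the log2 ratio. Root hair genes stand at a median of -2.74 with Al in wild type and -1.78 in the pair labelled arf10/16, and jasmonate genes at 1.98 between the untreated libraries.

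The last comparison is the one the series names, whether the Al response differed between the genotypes. Root hair genes were lower with Al in both pairs, and less so in the pair labelled arf10/16. Root cap genes had a median of -0.74 in wild type and 0.65 in the pair labelled arf10/16. By the rule of size, 2 of 8 were higher and 4 lower in wild type, against 4 and 0 in the other pair. Jasmonate genes had medians of 0.75 and -0.58. Of 15, 5 were higher and 1 lower in wild type, against 1 and 2 in the other pair. Between the genotypes their median was already 1.98 without Al, and 1.01 with Al. Glutathione S-transferases had medians of 1.15 and -0.02. Of 31, 15 were higher and 5 lower in wild type, against 9 and 6. The root hair list had a median difference of 1.02 on the log2 scale (8 of 15 past the rule; percentile 100), with PRP1 at 1.54 (0.85 to 2.38), RHD6 at 1.49 (0.68 to 2.47) and SHV2 at 1.43 (0.74 to 2.26). The jasmonate list had a median of -1.31 (8 of 15; below all random lists) and the glutathione S-transferases -0.67 (11 of 31 lower and 2 higher; below all random lists), with GSTF7 at -2.21 (-2.42 to -2.02) and GSTF2 at -2.03 (-2.21 to -1.86). By the rule of size 488 differences were positive and 714 negative, while simulated unchanged libraries with the estimated dispersion gave 590 and 568. That dispersion was itself estimated from the departure from additivity, so this simulation does not decide whether the total is above chance; with counting error alone it gave 171 and 128. No difference was tested.

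Among genes with a symbol and at least 50 reads in 1 library, the largest negative differences past the rule of size were in CRK11 (-3.28, -3.89 to -2.81), TH8 (-2.91, -6.41 to -1.01), WRKY75 (-2.87, -5.42 to -1.67), BCB (-2.86, -3.96 to -2.10) and PLA2A (-2.72, -3.4 to -2.2). The largest positive ones among the same genes were in PDC3 (2.85, 1.45 to 4.97), CYP705A3 (2.82, 0.82 to 6.24), CSLB02 (2.64, 1.53 to 4.50), sks15 (2.62, 1.78 to 3.61) and CER4 (2.28, 0.66 to 4.92). Early auxin genes had a median difference of -0.53 (4 of 25 lower), with BRU6 at -1.90 (-2.33 to -1.51) and GH3.3 at -1.15 (-2.48 to -0.04). EIR1 had a difference of 1.12 (0.71 to 1.55). Al tolerance genes had a median of -0.26 with 1 of 14 higher, ALS3, and 1 lower, BCB. The dehydration list had a median of -0.92 (5 of 11 lower), the immune list -0.43 (3 of 12 lower) and the root cap list 1.28 (2 of 8 higher). Of the wall lists, 3 of 7 pectin enzymes were higher (median 0.60), 6 of 22 xyloglucan endotransglucosylase/hydrolases were higher and 1 lower (median 0.26), 1 of 15 expansins was higher (0.42) and 0 of 10 cellulose and callose synthases passed (0.25).

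Of the 714 negative differences, 502 were in genes higher in the untreated library labelled arf10/16, and 442 in genes higher with Al in wild type; both ratios enter the difference with a negative sign, so such overlap arises in part by construction. Of the 488 positive ones, 340 were lower with Al in wild type and 102 were lower in the untreated library labelled arf10/16. The Al response of wild type and the untreated genotype difference share the untreated wild-type library; their covariance over genes was 0.318, against 0.111 in simulated unchanged libraries (difference 0.206), and their correlation 0.37 against 0.51. With 1 library no split of that control is possible, so part of the relation may come from it. The 3 independent contrasts of the 4 libraries are the mean Al effect, the mean genotype effect and the difference of responses divided by 2. Because of that division, 2-fold in the last contrast is a larger difference of responses than 2-fold in the rule of size. In these contrasts 3462 genes reached 2-fold for Al, 1042 for genotype and 276 for the last. The deposited RPKM gave 3845, 1387 and 613. In simulated unchanged libraries the numbers were 113, 117 and 108. That simulation uses the dispersion estimated from the departure from additivity, so it does not decide on the last of these.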

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

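All tests below were chosen after the results they weigh had been seen, except 3 whose predictions were written before their values: reads of other auxin response factors, thinned libraries, and genes alike in the untreated libraries. Intervals of medians in this section come from 10000 resamplings of the genes, or of single gene and treatment values for the neighbours of ARF10. Genes of the same libraries are not replicates, so these intervals do not cover the spread between plants or cultures. In 4 genes past the rule of size the Al response went in opposite directions in the genotypes, a difference between groups that was not tested because there are no replicates. AT1G65570, a pectin lyase-like protein, is in the fixed root cap list and is counted in that list's result above. This gene was lower with Al in wild type (log2 -2.64; 57 against 7 reads) and higher in the pair labelled arf10/16 (2.14; 2 against 14 reads), a difference of 4.78 (3.33 to 7.78). The other 3 were higher with Al in wild type and lower in the other pair: AT1G17147, a VQ motif protein (1.98 and -1.38), AT5G56960, a bHLH protein (1.77 and -1.28), and AT5G39580, a peroxidase (1.05 and -1.30). In that order they had 5, 4 and 12 reads in untreated wild type, against 84, 143 and 153 in the untreated library labelled arf10/16. With Al they had 25, 18 and 26 reads in wild type, against 28, 52 and 55. Each of the 4 genes differed more between the genotypes without Al than with Al. Displaced untreated levels therefore cannot be told apart from an opposite response to Al.

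ARF10 was higher in the libraries labelled arf10/16. All 9 other measured auxin response factor loci together had 858 reads in untreated wild type, fewer than the 3710 that ARF10 gained. Reads counted at those loci therefore cannot be the whole source. Other members were below the filter, with ARF6 and ARF8 at 1 read each in untreated wild type. Whether reads of such loci were lost in counting was not tested, so uncounted reads are not excluded. The 7 measured loci within 5 positions of ARF10, with both treatments pooled, had a median log2 ratio of -0.14 (-0.31 to -0.03), which argues against more reads over the whole segment. That interval treats the ratios of a locus with and without Al as separate values, so it may be too narrow. An exchange of genotype labels cannot be told apart from an effect of the mutant line, since ARF16 was lower (-0.85) and ARF10 higher (4.86) in the libraries labelled arf10/16. No biological explanation was tested, and an insertion that raises part of the ARF10 transcript may be one.

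Jasmonate and immune genes were higher in the untreated library labelled arf10/16 (median 2.02 over the 23 genes past the rule). With Al, in other libraries, the same genes had a median of 1.03 (0.84 to 1.26), which argues against a low untreated wild-type library as the whole cause. Under scaling by total counts the untreated median was 2.00 (1.78 to 2.25), held there by WRKY18, a gene at 0 reads in untreated wild type; the medians of the whole lists went from 1.98 to 1.86 (jasmonate) and from 1.93 to 1.82 (immune), which excludes scaling as the whole cause. Handling or time of harvest of the single cultures cannot be told apart from genotype: 9 clock genes had a median absolute log2 ratio of 0.19 (0.08 to 0.97), and other handling was not measured.

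Al responses were smaller in the pair labelled arf10/16, with 68.8% of the shared genes larger in wild type. With all libraries thinned to 2066080 reads the share was 68.4%, which excludes unequal depth. Among 700 shared genes with untreated libraries within 0.25 log2 of each other it was 63.9%, which excludes displaced untreated levels as the whole cause. One weaker exposure acting on every gene alike cannot be told apart from a genotype effect: the slopes of the responses in 11 lists, from 0.60 for early auxin genes to 0.87 for Al tolerance genes, had a spread not shown to exceed that of genes permuted among the lists (permutation p = 0.135). These lists were kept for a median of at least 0.8 in size in wild type, and the slopes were taken on the wild-type values. Noise in those values can lower the slopes, so slopes below 1 do not by themselves show smaller responses. With 1 library per group, a genotype effect was not tested.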

How the results depend on the processing

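No named gene past the rule of size and no list median outside the central range of random lists changed sign, but the Al responses had more genes higher than lower under TMM and more lower than higher under total counts and RPKM. Of the counts of genes, 73 of 98 stayed within 1.5 times; 433 of 435 list medians, 1630 of 1644 values of named genes and 14 of 15 correlations and contrasts stayed within the spread or factor set for them. Leaving out 1 library was not applicable, since each group has 1 library and the additive model then has no residual degree of freedom. Loci with a single model are fewer genes and gave 1383 higher and 1130 lower for Al in wild type, 1037 and 863 for Al in the pair labelled arf10/16, 758 and 235 for genotype without Al, 160 lower for genotype with Al, and 303 and 456 for the difference of responses. Under total counts, 607 genes were lower for genotype without Al. An interval wholly beyond 1.5-fold is stricter and left 141 lower for genotype without Al, 332 higher and 85 lower for genotype with Al, and 167 and 356 differences. The deposited RPKM gave 974 lower for genotype without Al, 744 lower with Al, 1257 and 1362 differences, and 486 genes shared by both genotype comparisons. DESeq2's Wald test gave 1749 genes for Al and 176 for genotype. The genotype effect had 919 genes without the filter, 120 transcript models when models were kept apart, and 0 genes with limma-trend on RPKM. The root hair median for genotype without Al was 0.12 under total counts. Apart from the single-model loci and the stricter interval, the cause of these moves was not tested.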

Other observations

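The groups in this part were chosen after the main results had been seen, and not all of the 18 families are described. Genes of senescence and autophagy were higher with Al in both genotypes, with medians of 1.62 in wild type and 1.27 in the pair labelled arf10/16, and 12 of 18 rose and 1 fell in edgeR's quasi-likelihood test. NBR1, a receptor that brings cargo to autophagy, was 9.37-fold higher in wild type (8.72 to 10.08) and 6.83-fold higher in the other pair (6.41 to 7.28). NAC6, a regulator of leaf senescence, was 14.0-fold higher (9.49 to 21.6) and 12.9-fold higher (9.10 to 18.9). Measured genes of the ATG8 autophagy family changed less than NBR1, from 1.24-fold (ATG8F) to 2.97-fold higher (APG8H) in wild type. In the other pair they ran from 1.07-fold lower (ATG8E) to 2.47-fold higher (APG8H). ATG8E, ATG8F and ATG8G did not pass edgeR's quasi-likelihood test, while the other measured members of that family rose. Of 56 NAC factors 35 rose and none fell (medians 1.42 and 1.1). Of 40 proteasome subunits 12 rose and none fell (medians 0.54 and 0.49).

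Ribosomal proteins, extensins, aquaporins and tubulins had medians below 0 with Al in both pairs. Class III peroxidases did too but split, since 18 of 57 rose and 25 fell (medians -0.59 and -0.61). Arabinogalactan proteins also split, since 9 of 25 rose and 10 fell (medians -0.87 and 0.06). Of 233 cytosolic ribosomal proteins 96 fell and 2 rose (medians -0.78 in wild type and -0.49 in the pair labelled arf10/16). Of 36 extensins, wall proteins abundant in root hairs, 22 fell and 5 rose (medians -1.92 and -1.31). With Al, 14 extensins were higher by the rule of size in the library labelled arf10/16 and 1 lower (median 0.79). Without Al, 3 were higher and 2 lower (median 0.10). Between genotypes, 1 of the 36 was higher in edgeR's quasi-likelihood test and 0 lower. Of 19 aquaporins 11 fell and 1 rose (medians -1.36 and -0.96), and of 20 tubulins 7 fell (medians -0.81 and -0.36). By the rule of size, 27 of 56 WRKY factors were higher in the library labelled arf10/16 without Al and 11 with Al, and none was lower (medians 0.85 and 0.55). In edgeR's quasi-likelihood test of genotype 12 of these 56 were higher and 0 lower.

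AT4G29200, a gene related to beta-galactosidases and picked after its values were seen, had 162 reads in wild type and 1 in the library labelled arf10/16 without Al (146-fold lower, 25.8 to 5787), and 105 and 1 with Al (89.3-fold lower, 15.7 to 3559). Of the 278 genes with the same genotype difference in both treatments, 6 lay within 50 positions of ARF10 or ARF16. ARF10 itself, already known to differ, is among the 6. An even spread over the measured loci would give 2.09, and the excess was not tested.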
